A study of Mus musculus with 32 samples.

How the data were processed

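The series holds 32 RNA sequencing libraries from primary mouse astrocytes in 8 groups of 4: Control, PBM, LPS and LPS+PBM, each at 4 h and 24 h. Per the labels, total RNA was taken with Trizol, and full-length cDNA was made with an oligo-dT primer and template switching, amplified over several PCR cycles and sequenced on an Illumina NovaSeq. No molecular barcodes are named, so PCR copies could not be told from separate molecules.

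The authors scaled fragments to transcript length and library size to make FPKM values, and the table of genes was used as deposited, with 2 decimals, for 21899 Ensembl genes in 32 columns. Per the submitters' processing notes, fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM were used with the mouse genome build mm10. Which tool made the FPKM values, and the strand used in counting, are not given in the sources used here. Of the IDs, 21806 (99.58%) matched GENCODE M21 (GRCm38, the same assembly as mm10), which gave names, gene types and coordinates, and 21406 were protein-coding. In all, 6787 genes were at 0 in all libraries, 5634 were above 0 in all, and 19 symbols stood for more than 1 gene ID and were kept apart by ID.

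A gene with a single annotated transcript should have FPKM values in whole steps of 1 fragment. The number of fragments behind each library was therefore inferred from those steps, in 673 of 4310 such genes. Over all 4310, 92.27% of 23614 values above 0 and of up to 20 fragments were whole within 0.05 of a fragment. This inference was made after the data were seen, and the resulting depth is very low for a bulk library. Same-group libraries correlated at 0.8792 to 0.8925 across genes (48 pairs) and libraries of different groups at 0.8497 to 0.8924 (448 pairs).

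The groups, tests, gene lists, naming rule and most other settings were fixed before the data were examined. The design held a branch for counts, which did not apply, since only FPKM values were given. The test was limma on log2(FPKM + 1) with an intensity trend and robust variances, on genes with a mean of at least 1 FPKM in at least 1 fitted group. The 16 libraries of a time were fitted together, and all 32 for differences between times. P-values were adjusted by Benjamini and Hochberg, and a gene was called changed at an adjusted p under 0.05. Replicate numbers recur in all groups, so it was checked whether they pair the libraries. Over 8990 genes, residuals correlated at -0.025 to 0.035 for the same number (48 pairs, 0 of them above 0.1) and at -0.047 to 0.043 for different numbers (144 pairs). At this depth counting noise in low genes could hide a pairing, so the check does not exclude one. The numbers were not used in the main fit.

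A total of 35 lists were fixed: cytokines and chemokines, NF-kappaB feedback and target genes, type I interferon response, JAK-STAT components, SOCS family and STAT5 target genes. For astrocytes these were pan-reactive, A1 reactive, A2 reactive and homeostatic genes, and for immunity complement, antigen presentation, inflammasome and pyroptosis, and Toll-like receptor signalling. The others were immediate early genes, nuclear cytochrome c oxidase, the other nuclear respiratory complexes, mitochondrially encoded genes, mitochondrial biogenesis and dynamics, glycolysis, antioxidant and NRF2 targets, heat shock, unfolded protein and integrated stress response, hypoxia, cell cycle, cholesterol synthesis, neurotrophic and growth factors, extracellular matrix, circadian clock and ribosomal proteins, with markers of microglia, oligodendrocyte lineage, neurons, endothelial and mural cells, fibroblasts and meninges, and ependyma. Lists were tested by camera in limma with the preset correlation of 0.01 where at least 5 members were tested, adjusted within a comparison. ependymal markers fell short at 24 h, which left 34. The alternative estimates the correlation from the data.

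Genes named were 13 study genes (Stat5a, Stat5b, Socs3, Cish, Il6, Tnf, Il1b, Ccl2, Cxcl10, Nos2, Lcn2, C3 and Gfap), the 10 largest rises and 10 largest falls by fitted fold change, and up to 4 members of each list with the smallest adjusted p. The largest changes had to pass, keep the groups fully separated and reach a mean of 5 FPKM in the higher group, without predicted or clone names. Where none passed, 3 per direction with the smallest p were named as not passing. For interactions and time differences, up to 5 per direction were named without the separation rule.

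Each result was also computed, by choices made at that stage, with a pseudocount of 0.1, no filter on low values, quantile normalization, other libraries in the fit, the replicate number as a block, library quality weights, leaving out each library, the estimated correlation, and LPS libraries split in pairs for the overlap. Chosen after seeing the data were limma-voom on approximate fragments, leaving out the 6 last-listed libraries, and leaving out each library for the lists and the overlap.

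A self-test on simulated fragments at the inferred depth (dispersion 0.05, 200 genes changed, LPS against Control at 4 h) called 0%, 40%, 68% and 96% of genes raised 2-, 4-, 8- and 16-fold, and 0%, 20%, 44% and 56% of genes lowered as much. Of 83 calls 2 were unchanged genes, and in the simulated LPS+PBM against LPS comparison 8 of 94. Genes changed 4-fold were called in 83.3% of cases over 10 fragments and in 5.9% under 3. In a separate simulation of PBM against Control at 4 h (12342 genes), a list of 20 genes shifted 1.8-fold had a camera p of 6.89e-07, while 5 of 50 random lists had p under 0.05. The software was R 4.3.3 with limma 3.58.1 and the data.table package 1.17.8, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.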

Results

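Gene expression was profiled by RNA sequencing in primary mouse astrocytes, the star-shaped glial cells that support neurons and take part in brain inflammation. Cultures were untreated (Control), treated with light (photobiomodulation, PBM), given lipopolysaccharide (LPS, a bacterial cell wall component sensed by Toll-like receptor 4), or given LPS and PBM together (LPS+PBM). Each treatment was sampled at 4 h and at 24 h, with 4 libraries in each of the 8 groups and 32 libraries in all. The study's title names a STAT5A/SOCS3 axis, so the central question was what PBM did to the LPS response and to Stat5a and Socs3. The wavelength, dose and exact timing of the light were not given in the sources used here. The labels do not say that replicates came from separate cultures, so p-values measured only the spread between these samples, which may be technical.

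Depth was inferred from the steps of the FPKM values, at 130756 to 143821 fragments per library (median 137293). At that depth 1 fragment in a transcript of 1 kb was worth 6.95 to 7.65 FPKM, and the counting floor of 3 fragments was 20.9 to 22.9 FPKM. Between 10136 and 10777 genes were above 0 in a library, and mitochondrially encoded genes took 7.12% to 9.55% of the FPKM total. Ppia, a gene that every cell uses, was listed at 0 in 14 libraries and reached 25.8 FPKM at most, so a value of 0 is given here as listed at 0 and not as absence. Fold changes are differences of group means on the log2(FPKM + 1) scale and stand with their SE. For low genes they depend on the added 1 and on libraries listed at 0. They can therefore lie above or below the change in mean FPKM. Gene levels are mean FPKM ± SD (n = 4).

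The LPS libraries were first compared with Control at 4 h, to describe the inflammatory response itself. Chemokine and interferon genes rose. Ccl2, the monocyte chemoattractant (ENSMUSG00000035385, GRCm38, chromosome 11, 82035571 to 82037453, plus strand), stood at 37.7 ± 7.84 FPKM in Control and at 1885 to 2062 FPKM with LPS, a log2 fold change of 5.68 ± 0.20 (limma adjusted p = 1.02e-12). Cxcl10, an interferon-induced T cell chemoattractant (chromosome 5, 92346638 to 92348889, minus strand), went from 21.5 ± 10.0 to 1224 ± 161 FPKM, a log2 fold change of 5.87 ± 0.27 (adjusted p = 6.45e-11). Tnf rose by 3.34 ± 0.50 on the log2 scale (7.20 ± 2.72 to 80.0 ± 18.8 FPKM, adjusted p = 0.000386). Il6 (chromosome 5, 30013114 to 30019981, plus strand) rose by 4.03 ± 0.85 (30.1 ± 15.4 to 460 ± 57.3 FPKM, adjusted p = 0.0107).

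By fitted fold change, the steepest rises were those of Saa3, an acute-phase protein (6.59 ± 0.66), Rsad2, the antiviral enzyme viperin (6.40 ± 0.52), Acod1, which makes itaconate (6.28 ± 0.56), Ccl4 (6.11 ± 0.85), Ccl5 (6.02 ± 0.94), Mx1, an interferon-induced GTPase (6.01 ± 0.75), followed by Cxcl10 and the neutrophil chemoattractant Cxcl1 (5.84 ± 0.77). Saa3 was listed at 0 in 3 of the 4 Control libraries and at 12.57 in the other, and reached 185 ± 29.1 FPKM with LPS. Ccl20, Nos2 (inducible nitric oxide synthase) and Lcn2 (the iron-binding lipocalin-2) were listed at 0 in all 4 Control libraries and at 61.0 ± 38.4, 48.9 ± 9.85 and 29.6 ± 6.96 FPKM with LPS. Il1b was listed at 0 in 2 Control libraries, with 5.51 and 5.34 FPKM in the others, and at 60.3 ± 8.64 FPKM with LPS (adjusted p = 6.69e-05). C3, the central complement component, rose by 4.07 ± 0.51 (adjusted p = 4.92e-05).

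Of the 25 cytokines and chemokines tested, 17 rose (22 when adjusted over the list alone), with a median log2 fold change of 4.03 and a camera adjusted p = 3.82e-07 with an estimated correlation. Lif rose by 3.79 ± 0.26 and Ccl7 by 5.06 ± 0.38. Of the 26 NF-kappaB feedback and target genes, 16 rose (24 adjusted over the list alone, median 2.33, adjusted p = 8.22e-08 with an estimated correlation). These included the adhesion molecules Vcam1 (4.05 ± 0.20) and Icam1 (3.39 ± 0.22), the pentraxin Ptx3 (3.08 ± 0.22) and Ptgs2, which encodes cyclooxygenase-2 (1.51 ± 0.12). Of the 33 type I interferon response genes, 25 rose (32 adjusted over the list alone, median 2.25, adjusted p = 3.82e-07 with an estimated correlation). Among them were Ifit3 (2.59 ± 0.14), Ifit2 (3.72 ± 0.23), Ifit1 (2.85 ± 0.20) and Ifit3b (3.27 ± 0.24). Members of this family resemble each other in sequence, so the split of reads between them is uncertain.

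Of the 28 JAK-STAT components, 4 rose (7 adjusted over the list alone, median 0.52, adjusted p = 0.00123 with an estimated correlation). Among those that rose were Stat2 (1.96 ± 0.28), the oncostatin M receptor Osmr (1.73 ± 0.35) and the phosphatase Ptpn2 (1.98 ± 0.43). Antigen presentation genes had 7 of 20 that rose (12 adjusted over the list alone, median 1.05, adjusted p = 0.000129 with an estimated correlation). The immunoproteasome subunit Psmb8 (2.38 ± 0.32) and the class I genes H2-Q4 (1.92 ± 0.30) and H2-K1 (1.12 ± 0.23) were among them. Tap1 (2.46 ± 0.26) overlaps Psmb9 in the annotation, so its value is uncertain. The inflammasome list had 4 of 12 that rose (5 adjusted over the list alone, adjusted p = 0.0132 with an estimated correlation). Members included Il1rn, the interleukin-1 receptor antagonist, at 5.32 ± 0.71. The Toll-like receptor list had 2 of 25 that rose (7 adjusted over the list alone, adjusted p = 0.0423 with an estimated correlation), and Tlr2 rose by 4.67 ± 0.45.

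Of the genes described as induced in all reactive astrocytes, 6 of 12 rose (8 higher and 1 lower adjusted over the list alone, adjusted p = 5.7e-05 with an estimated correlation). Among them were Timp1 (1.54 ± 0.11) and the hyaluronan receptor Cd44 (0.93 ± 0.10). The A1 list, named for neuroinflammatory astrocytes, had 4 of 11 that rose (5 adjusted over the list alone, adjusted p = 0.00293 with an estimated correlation). Members included Gbp2 at 2.59 ± 0.22 and Iigp1 at 2.94 ± 0.33. The A2 list, named for ischemia, had 2 of 11 that rose, Ptx3 and Ptgs2 (4 adjusted over the list alone, adjusted p = 0.00651 with an estimated correlation). Gfap, the astrocyte intermediate filament, stood at 42.3 ± 7.84 FPKM in Control and 30.6 ± 9.84 FPKM with LPS (log2 fold change -0.48 ± 0.30, adjusted p = 0.587).

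Of the 17 immediate early genes, which encode rapidly induced transcription factors and regulators, 3 fell with LPS (1 higher and 11 lower adjusted over the list alone, median -0.62, adjusted p = 0.00892 with an estimated correlation). Those that fell were Fos (-1.46 ± 0.19), Nr4a1 (-1.10 ± 0.25) and Ier2 (-1.27 ± 0.30). The homeostatic astrocyte list, which holds glutamate and potassium handling genes, had 16 of 20 members below 0 and none that passed (3 lower adjusted over the list alone, median -0.67, adjusted p = 0.000944, and adjusted p = 0.0878 with an estimated correlation). Microglia markers had 13 of 17 members below 0 and none that passed, over all genes or over the list alone (median -0.57, adjusted p = 0.0113, and adjusted p = 0.162 with an estimated correlation). Among the steepest falls were Pcgf2, a polycomb subunit (-3.87 ± 0.95), Fcgr3, an Fc receptor (-3.54 ± 0.91), Efna4 (-3.45 ± 0.83), Slc37a2 (-3.42 ± 0.66) and Unc13b (-3.27 ± 0.68). Chchd6, Cfap300, Rab4a, the iron exporter Slc40a1 and Mettl25 were listed at 0 in all 4 LPS libraries and at means of 8.04 to 14.5 FPKM in Control.

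Stat5a (ENSMUSG00000004043, chromosome 11, 100859351 to 100885169, plus strand) was listed in Control at 0, 0, 6.02 and 3.87 FPKM and with LPS at 4.73, 39.6, 16.1 and 11.9 FPKM. Over each group, these values rest on about 3 fragments in Control and about 25 with LPS. The log2 fold change of Stat5a was 2.64 ± 0.81, which did not pass over all genes (adjusted p = 0.12) and passed over the 13 study genes alone (adjusted p = 0.00623). Most of those 13 genes had far smaller p with LPS, so this adjustment barely corrects the unadjusted limma p of 0.00431. The 3' end of Stat5a overlaps that of Stat3 (chromosome 11, 100885098 to 100939540, minus strand), and the strand used in counting was not stated, so its level is uncertain. Socs3, a feedback inhibitor of cytokine signalling (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047, minus strand), had a log2 fold change of -0.84 ± 0.66 (adjusted p = 0.66). Stat5b (0.24 ± 0.55) and Cish, a STAT5 target (1.28 ± 0.75), did not pass either, and the SOCS and STAT5 target list had no member that passed, over all genes or over the list alone (adjusted p = 0.636).

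Over the 13247 genes tested at 4 h, limma called 295 genes, 232 higher and 63 lower with LPS, of which 266 changed at least 2-fold. 1599 genes had an unadjusted p under 0.05 where chance gives 662. In 964 of all genes tested (7.28%), every library of 1 group lay above every library of the other, and 287 of the 295 called genes were among them. Chance gives such separation in 2.86% for values without ties, and in less where libraries tie at 0. Il6 and Tnf lost their calls with a pseudocount of 0.1 in place of 1, and of 16 settings Pcgf2 lost its call in 9, Fcgr3, Chchd6 and Slc40a1 in 8, Efna4 in 7, Ier2 in 6, Nr4a1 in 5, Ptpn2 in 3 and Ccl5, Cfap300, Unc13b and Mettl25 in 1. Nuclear cytochrome c oxidase genes (adjusted p = 0.852), the other nuclear respiratory complexes (0.85), mitochondrially encoded genes (0.612), mitochondrial biogenesis (0.612), glycolysis (0.824), heat shock (0.364), the unfolded protein response (0.724), ribosomal proteins (0.159) and complement (0.0747) did not move as lists by camera. The same held for markers of oligodendrocytes (adjusted p = 0.741), neurons (0.288), endothelial and mural cells (0.159), fibroblasts (0.087) and ependymal cells (0.364).

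**Figure D1:**
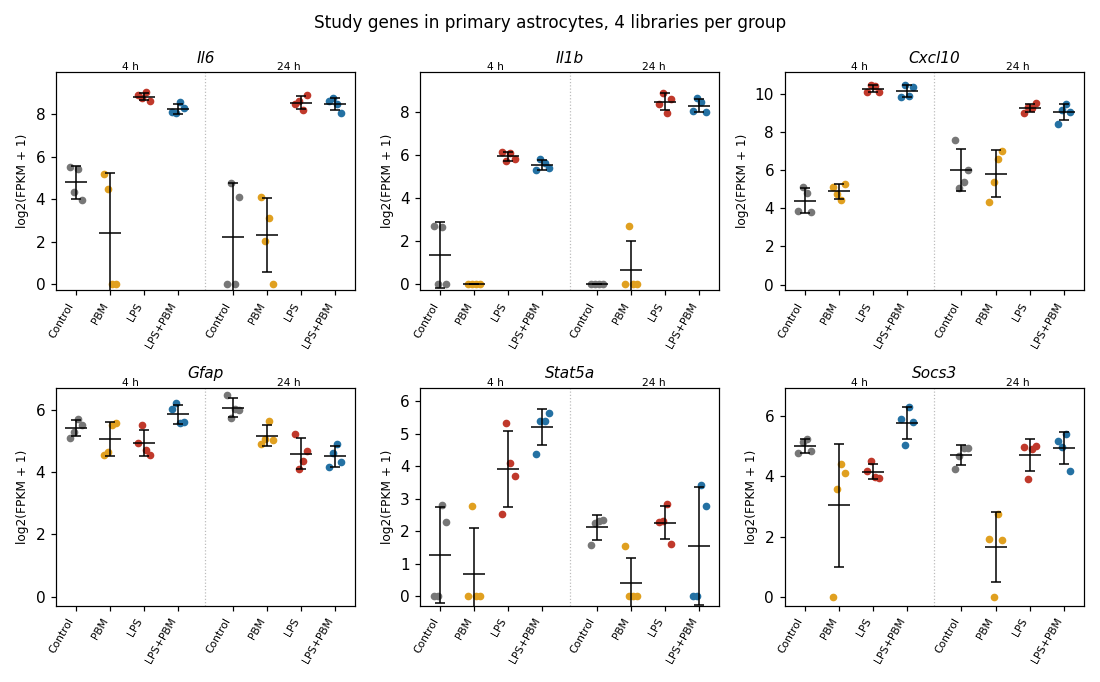
FPKM of Il6, Il1b, Cxcl10, Gfap, Stat5a and Socs3 on the log2(FPKM + 1) scale (vertical axis) in the 8 groups (horizontal axis); points are the 4 libraries of a group, and the bar is their mean ± SD. Il6 and Cxcl10 lie higher in every LPS and LPS+PBM library than in the Control libraries of the same time, while Socs3 is lowest with PBM at 24 h, between 0 and 5.74 FPKM.

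The same comparison was made at 24 h. Saa3 reached 4166 ± 457 FPKM with LPS, while it was listed at 0 in 3 Control libraries and at 12.59 in the other (log2 fold change 11.08 ± 0.84, limma adjusted p = 7.53e-08). Il6 reached 382 ± 75.4 FPKM (6.35 ± 0.92, adjusted p = 0.000299), Lcn2 349 ± 55.1 FPKM (7.63 ± 0.54, adjusted p = 2.78e-08) and Ccl5 1578 ± 131 FPKM (7.14 ± 0.83). Il1b was listed at 0 in all 4 Control libraries and at 362 ± 95.1 FPKM with LPS, and Il1a rose by 7.94 ± 0.43 to 364 ± 22.4 FPKM. Gfap (chromosome 11, 102887336 to 102900912, minus strand) fell by 1.47 on the log2 scale (SE 0.30, 67.6 ± 15.2 to 24.4 ± 9.12 FPKM, adjusted p = 0.00899).

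Ccl2 (5.86 ± 0.46), Cxcl1 (8.28 ± 0.76), Cxcl10 (3.26 ± 0.50), Tnf (3.02 ± 0.65, adjusted p = 0.0139) and C3 (3.58 ± 0.51) rose too. Cxcl5, Acod1, Ccl20 and Nos2 were listed at 0 in all Control libraries and at 111 ± 18.2, 95.6 ± 20.7, 86.3 ± 39.1 and 52.5 ± 6.87 FPKM with LPS. Of 24 cytokines and chemokines, 20 rose (21 adjusted over the list alone, median 3.69, camera adjusted p = 1.8e-06 with an estimated correlation). Of 26 NF-kappaB genes 16 rose (24 adjusted over the list alone, adjusted p = 1.84e-05 with an estimated correlation). Members included Ptx3 at 3.83 ± 0.19 and Vcam1 at 2.96. The interferon list had only 4 of 33 that rose (10 adjusted over the list alone, median 0.50, adjusted p = 2e-10, and adjusted p = 0.0869 with an estimated correlation), Gbp2 (1.32 ± 0.18), Gbp5 (3.45 ± 0.62), the nucleic acid sensor Zbp1 (adjusted p = 0.0163) and Parp14 (0.94 ± 0.23).

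Complement genes had 3 of 13 that rose (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.0043 with an estimated correlation). Those that rose were C3, Cfb (4.45 ± 0.80), and C5ar1, the C5a receptor, which was listed at 0 in Control and at 45.5 ± 15.6 FPKM with LPS. Antigen presentation genes had 6 of 20 that rose (13 adjusted over the list alone, adjusted p = 0.000943 with an estimated correlation). Members included H2-Q4 at 2.79 ± 0.27, H2-K1 at 1.98 ± 0.22 and H2-D1 at 1.22 ± 0.15. These class I genes are close relatives, so reads could be split between them. Toll-like receptor genes had 3 of 24 that rose (3 adjusted over the list alone, adjusted p = 0.00858 with an estimated correlation). Members included the LPS co-receptor Cd14 at 5.09 ± 0.72. JAK-STAT components had 4 of 28 that rose (5 adjusted over the list alone, adjusted p = 0.00858 with an estimated correlation). Members included Jak2 at 2.11 ± 0.23 and the shared cytokine receptor Il6st at 1.20 ± 0.28. The inflammasome list had 4 of 12 that rose (4 adjusted over the list alone, adjusted p = 0.0104 with an estimated correlation). Members included Il1rn at 3.76 ± 0.72 and Nlrp3 at 2.85 ± 0.63.

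Pan-reactive astrocyte genes had 7 of 13 that rose and 2 that fell (7 and 2 adjusted over the list alone, adjusted p = 0.0043 with an estimated correlation). Timp1 rose by 2.22 ± 0.13 and Steap4 by 4.27 ± 0.59, while Vim fell (-0.84 ± 0.08) beside Gfap. The A1 list had 4 of 12 that rose (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.0043 with an estimated correlation). The A2 list had 4 of 10 that rose and 1 that fell (4 and 3 adjusted over the list alone, adjusted p = 0.00933 with an estimated correlation). In the homeostatic list, 19 of 20 members were below 0 and 2 fell (4 adjusted over the list alone, median -0.84, adjusted p = 0.00858 with an estimated correlation). Those that fell were Glul, glutamine synthetase (-1.19 ± 0.23), and Apoe (-0.95 ± 0.21). All 23 cell cycle genes were below 0 and none passed over all genes (6 lower adjusted over the list alone, median -1.41, adjusted p = 0.00803 with an estimated correlation).

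Markers of other cell types moved beside these groups. Of 19 microglia markers, Fcer1g rose (1.21 ± 0.25) and 3 fell, Trem2 (-4.15 ± 0.64), C1qc (-1.67 ± 0.35) and Cd68 (-1.04 ± 0.26) (1 higher and 4 lower adjusted over the list alone, median -0.58, adjusted p = 0.0213, and adjusted p = 0.0555 with an estimated correlation). Of 9 endothelial and mural markers, the smooth muscle genes Acta2 (-0.65) and Tagln (-0.56) fell (2 lower adjusted over the list alone, adjusted p = 0.0418 with an estimated correlation). Steep falls were also fitted for Slc4a10, a bicarbonate transporter (-3.83 ± 0.57), the mitochondrial ribosomal protein gene Mrpl28 (-3.77 ± 0.87), Cryz (-3.76 ± 0.96), the glutamine transporter Slc38a3 (-3.73 ± 0.74), Elobl (-3.90 ± 0.94) and the chemokine receptor Cxcr4 (-3.19 ± 0.77). Extracellular matrix genes had 7 of 26 that rose (8 higher and 7 lower adjusted over the list alone), with the collagen cross-linker Lox at 1.00 ± 0.08 and the collagenase Mmp13 at 4.19 ± 0.45. The median was -0.02 and the mean 0.38, and the list was called higher (adjusted p = 0.00951, and adjusted p = 0.119 with an estimated correlation). The hypoxia list had none that passed either way (median 0.26, adjusted p = 0.0407, and adjusted p = 0.0869 with an estimated correlation). Septin4, Rgs10 and Rab4a were listed at 0 in all 4 LPS libraries and at means of 14.9, 17.1 and 13.3 FPKM in Control.

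Stat5a was listed at 1.95 to 4.09 FPKM in Control and 2.02 to 6.11 FPKM with LPS at 24 h (log2 fold change 0.14 ± 0.76, adjusted p = 0.991). Socs3 (0.00 ± 0.50) and Cish (2.45 ± 0.87, adjusted p = 0.182) did not pass over all genes. Cish passed over the 13 study genes alone (adjusted p = 0.0143), an adjustment that barely corrects its unadjusted limma p of 0.011, since most of those genes had far smaller p. Over 13278 genes, limma called 340, 215 higher and 125 lower, 284 of them at least 2-fold (1764 at an unadjusted p under 0.05, 664 by chance), and 325 had fully separated groups. Leaving out the 6 libraries whose columns stand last and out of order in the table, an alternative chosen after seeing the data, reduced the count to 159 and ended the calls of Gfap, Apoe and Tnf. Those 6 include LPS replicates 2 and 4 of this time, so the setting also removes replicates. Leaving out any 1 library of the comparison gave 242 to 280 calls. The loss of replicates cannot be told from other differences of these libraries. Tnf also lost its call with a pseudocount of 0.1, Apoe without Control replicate 1 or LPS replicate 3, and of 16 settings Rgs10 lost its call in 11, Parp14 in 10, Cryz, Cxcr4, Elobl and Cd68 in 9, Mrpl28 and Nlrp3 in 7, Zbp1 in 6, Il6st in 5, C1qc, Fcer1g and Il1rn in 2, and Gbp5, Rab4a, Septin4 and Tagln in 1.

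The difference between the LPS effect at 24 h and at 4 h was tested over all 32 libraries. The interferon genes Rsad2, Mx1 and Cmpk2 had smaller LPS effects at 24 h, by -5.78 ± 0.67, -5.36 ± 1.03 and -5.10 ± 0.67 on the log2 scale (limma adjusted p = 3.84e-06, 0.00657 and 2.79e-05). Rsad2 went from 359 ± 80.6 FPKM with LPS at 4 h to 48.1 ± 12.2 FPKM at 24 h, while its Control libraries stood at 5.92 FPKM or less at 4 h and at 32.2 ± 13.3 FPKM at 24 h. Cxcl10 also had a smaller effect at 24 h (-2.61 ± 0.61, adjusted p = 0.0347), and its Control level stood at 80.8 ± 72.1 FPKM at 24 h. Il1b reached 60.3 ± 8.64 FPKM at 4 h and 362 ± 95.1 FPKM at 24 h (adjusted p of the difference 0.00701).

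In all, 86 of 13937 genes differed, 26 with a more positive and 60 with a more negative LPS effect at 24 h than at 4 h, 77 of them at least 2-fold. C1galt1c1 (-4.49 ± 1.00) and Krr1 (-4.02 ± 0.88) followed the interferon genes. Cfap300, Ndufc1, Avpi1, C5ar1 and Clec4n had a more positive effect at 24 h, and each was listed at 0 in at least 3 libraries of Control at 24 h or of LPS at 4 h. The count was 52 with only the Control and LPS libraries fitted and 42 without the 6 last-listed libraries, and of 24 settings Clec4n lost its call in 16, Ndufc1 in 14, Krr1 in 9 and C1galt1c1 in 6. Among the 12588 genes tested at both times, 89 were raised by LPS at both (229 at 4 h and 213 at 24 h, 3.9 expected from independent lists) and 18 were lowered at both (63 and 123, 0.62 expected).

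Whether PBM altered the LPS response was asked by comparing LPS+PBM with LPS. At 4 h, no inflammatory study gene passed. Ccl2 differed by -0.05 (95% confidence interval -0.46 to 0.36), Cxcl10 by -0.12 (-0.68 to 0.43), Tnf by -0.05 (-1.09 to 1.00), Nos2 by -0.11 (-1.05 to 0.83), Il1b by -0.39 (-1.62 to 0.85) and Il6 by -0.58 (-2.36 to 1.20) on the log2 scale. Il6 stood at 397 to 529 FPKM with LPS and 263 to 378 FPKM with LPS+PBM, so all 4 LPS+PBM libraries lay below all 4 LPS libraries. Socs3 and Gfap were separated the other way. Of all genes tested in this comparison, 508 (3.83%) were fully separated. Chance gives 2.86% for values without ties, and less where libraries tie at 0. Socs3 stood at 17.0 ± 3.38 FPKM with LPS and 55.9 ± 18.9 FPKM with LPS+PBM (log2 fold change 1.61 ± 0.66, interval 0.23 to 3.00), which did not pass over all genes (limma adjusted p = 0.572) or over the 13 study genes (0.161). Stat5a was listed at 4.73 to 39.6 FPKM with LPS and 19.9 to 49.5 FPKM with LPS+PBM (interval of the log2 fold change -0.40 to 3.00, adjusted p = 0.756). Gfap stood at 30.6 ± 9.84 and 58.4 ± 12.9 FPKM (0.93 ± 0.30, adjusted p = 0.458, and 0.0859 over the study genes).

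The 17 immediate early genes were higher as a list with LPS+PBM, with 15 members above 0, none passing over all genes and 5 adjusted over the list alone (median 0.44, camera adjusted p = 6.32e-07, and adjusted p = 0.0282 with an estimated correlation). Atf3, a stress-induced transcription factor, stood at 12.3 ± 4.87 FPKM with LPS and 38.9 ± 15.5 with LPS+PBM, Junb at 118 ± 20.9 and 189 ± 17.4, and Fosb at 58.1 ± 9.37 and 96.3 ± 10.9. The homeostatic astrocyte list had 18 of 20 members above 0 (none passing, over all genes or over the list alone, median 0.71, adjusted p = 1.3e-05), with Sox9, an astrocyte transcription factor, at 1.21 ± 0.40 and Ndrg2 at 1.52 ± 0.57. Cholesterol synthesis genes had 18 of 20 above 0 (none passing, 2 adjusted over the list alone, median 0.52, adjusted p = 6.13e-05), with Insig1 at 1.84 ± 0.40. Circadian clock genes had 14 of 15 above 0 (none passing, 1 adjusted over the list alone, adjusted p = 0.00534), and the SOCS and STAT5 target list 16 of 20 (none passing either way, median 0.50, adjusted p = 0.0181). Each of these 4 lists had an adjusted p = 0.0509 with an estimated correlation. The antioxidant and NRF2 target list had 15 of 20 above 0 (none passing, 2 adjusted over the list alone, adjusted p = 0.00534, and adjusted p = 0.0687 with an estimated correlation). Members included the heme-degrading enzyme Hmox1 at 0.82 ± 0.20.

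Cytokines and chemokines (adjusted p = 0.998), NF-kappaB genes (0.275) and interferon genes (0.204) did not move as lists. The genes with the smallest p were Rab4a, listed at 0 with LPS and at 10.8 ± 7.08 FPKM with LPS+PBM, Hbegf, an EGF receptor ligand (77.9 ± 13.1 and 163 ± 24.2 FPKM, 1.06 ± 0.19), the integrin Itga5 (0.60 ± 0.13), the ubiquitin ligase Ube3a (-1.96 ± 0.39), Nprl3 (-3.38 ± 0.69) and Znrd2, listed at 0 with LPS+PBM. None passed (adjusted p 0.19 to 0.211). By limma, 0 of 13247 genes passed, with 997 at an unadjusted p under 0.05 where chance gives 662. By limma-voom on approximate fragments, added after seeing the data, 16 passed (4 higher and 12 lower), and 1 passed with a pseudocount of 0.1 or without the last-listed libraries.

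**Figure D2:**
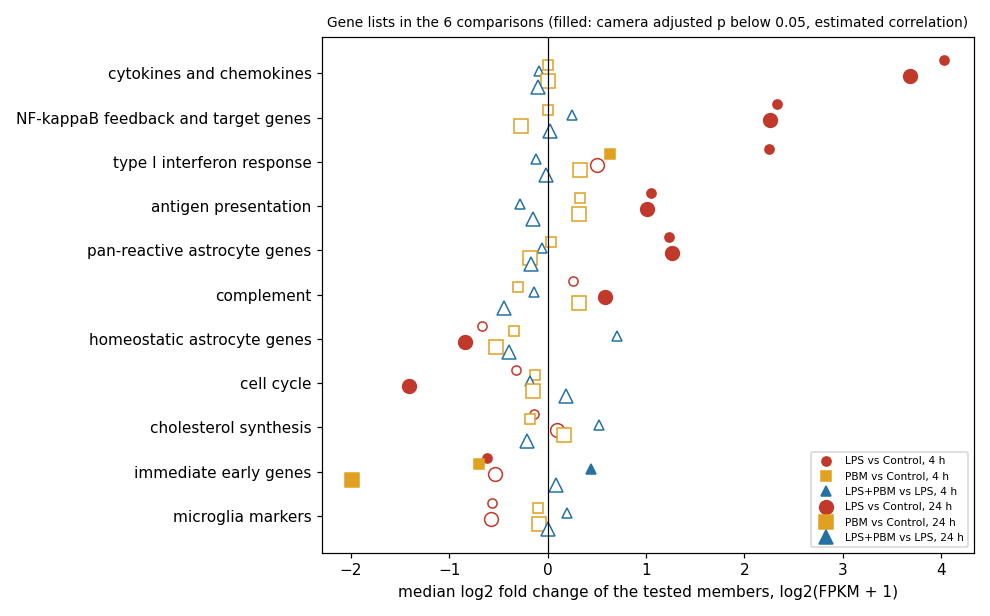
Median log2 fold change (horizontal axis) of the tested members of each gene list (vertical axis) in the comparisons at 4 h and 24 h; filled points have a camera adjusted p under 0.05 with an estimated correlation. The highest median for LPS is that of cytokines and chemokines at 4 h, at 4.03, while complement at 4 h stands at 0.26, and the list with the lowest median under PBM alone at 24 h is that of the immediate early genes, at -1.99.

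At 24 h, the gene called between LPS+PBM and LPS was Sprr2b, which encodes a small proline-rich protein of epithelia (limma adjusted p = 0.00149). It stood at 13.9 ± 5.46 FPKM with LPS and was listed at 0 in all 4 LPS+PBM libraries and in all Control and PBM libraries. Its mean with LPS lay under the counting floor of 20.9 to 22.9 FPKM for 1 kb, so the call rests on few fragments. Of 35 splits of these libraries into 4 and 4, the real one included, 17 called at least 1 gene. No study gene passed. Ccl2 differed by -0.10 (95% confidence interval -1.07 to 0.88), Il1b by -0.18 (-1.20 to 0.83), Il6 by -0.07 (-1.99 to 1.85), Lcn2 by -0.04 (-1.17 to 1.08) and C3 by -0.45 (-1.51 to 0.62) on the log2 scale. Socs3 differed by 0.23 (-0.82 to 1.28), Stat5a by -0.71 (-2.32 to 0.89) and Gfap by -0.09 (-0.72 to 0.54). Mitochondrially encoded genes were slightly higher as a list (11 of 13 above 0, none passing over all genes or over the list alone, median 0.13, adjusted p = 0.00928, and adjusted p = 0.799 with an estimated correlation).

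Sprr2b was the only gene of 13278 that limma called (683 at an unadjusted p under 0.05, 664 by chance). Its call ended with only the LPS and LPS+PBM libraries fitted or without the last-listed libraries, and limma-voom called 6 genes. The difference between the PBM effects in LPS at 24 h and 4 h passed for 0 of 13937 genes by limma (884 at an unadjusted p under 0.05, 697 by chance, 3 by limma-voom). Sprr2b (-5.03 ± 1.04), Slamf9 (-5.53 ± 1.16), Kpna2 (-4.48 ± 0.96), Tubd1 (4.38 ± 1.04), Sprr1a (5.69 ± 1.40) and Tbx18 (2.19 ± 0.57) had the smallest p, and none passed (adjusted p 0.251 to 0.56).

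Genes changed by LPS were then checked for movement back with PBM. The self-test, for LPS against Control at 4 h, called 0% of genes lowered 2-fold and 20% lowered 4-fold. Of genes raised as much it called 0% and 40%. A partial movement back could therefore go uncalled at this depth. At 4 h no gene was called between LPS+PBM and LPS, so no overlap with the LPS calls was possible. At 24 h 1 of the 215 raised genes, Sprr2b, fell, from a mean under the counting floor for 1 kb. Both comparisons use the same LPS libraries, which alone makes their fold changes covary: the covariance across genes was -0.261 at 4 h, with -0.25 simulated for no effect (a difference of -0.011), and -0.262 with -0.246 at 24 h (-0.015). With the LPS libraries split in pairs, so that the comparisons shared none, the median PBM fold change of LPS-raised genes was -0.101 to 0 at 4 h and -0.12 to -0.023 at 24 h on the log2 scale over the 6 assignments. For LPS-lowered genes it was -0.174 to 0.191 and -0.033 to 0.078. Camera on the LPS-raised genes gave unadjusted p of at least 0.282 at 4 h and from 0.0696 to 0.251 at 24 h over the same assignments.

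PBM alone was compared with Control. At 4 h, Mt1, the metal-binding metallothionein-1, rose from 18.6 ± 6.97 to 88.7 ± 34.5 FPKM (log2 fold change 2.18 ± 0.29, limma adjusted p = 0.00394). Nr4a1, an orphan nuclear receptor induced as an immediate early gene (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795, plus strand), fell from 83.4 ± 14.7 to 21.6 ± 3.48 FPKM (-1.90 ± 0.25, adjusted p = 0.00394). Fosb, an AP-1 subunit (chromosome 7, 19302696 to 19310051, minus strand), fell from 107.8 ± 24.6 to 36.9 ± 12.2 FPKM (-1.54 ± 0.24, adjusted p = 0.0138). Nfkbiz, an inducible regulator of NF-kappaB (chromosome 16, 55811375 to 55838899, minus strand), fell from 41.7 ± 7.21 to 14.3 ± 5.44 FPKM (-1.54 ± 0.25, adjusted p = 0.0146). Myl2 was listed at 0 in all PBM libraries and at 29.7 ± 18.9 FPKM in Control. The sixth called gene, 4930447C04Rik, named after its values were seen, was higher with PBM and listed at 0 in Control. Of the study genes, Socs3 (-1.96, 95% confidence interval -3.35 to -0.58) and Il6 (-2.39, -4.17 to -0.61) did not pass over all genes or over the 13 study genes (adjusted p = 0.0729 for each over the latter), and Stat5a was at -0.58 (-2.28 to 1.12).

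As a list, immediate early genes fell at 4 h: 16 of 17 were below 0, and 2 fell over all genes (9 adjusted over the list alone, median -0.70, camera adjusted p = 0.000366 with an estimated correlation). Fos stood at 277 FPKM in Control, 137 with PBM, 99.7 with LPS and 125 with LPS+PBM. Nr4a1 and Fosb were lowest with PBM, at 21.6 and 36.9 FPKM against 38.7 and 58.1 FPKM with LPS. Whether only the Control cultures stood apart was examined at 24 h, against groups that held LPS, and not at 4 h. Type I interferon genes were higher, with 32 of 33 above 0, none passing over all genes and 13 adjusted over the list alone (median 0.63, adjusted p = 0.00133 with an estimated correlation). Ifit3b was at 1.29 ± 0.24 and Ifit3 at 0.66 ± 0.14. The A1 (median 0.43, adjusted p = 0.213 with an estimated correlation), antigen presentation (0.33, adjusted p = 0.151 with an estimated correlation), hypoxia (0.52, adjusted p = 0.144 with an estimated correlation) and homeostatic lists (-0.34, adjusted p = 0.305 with an estimated correlation) passed only with the preset correlation. Over the list alone 1 A1 member was higher and 1 lower, 3 antigen presentation members were higher, and none passed in the other 2. Of 13247 genes, 6 passed by limma (2 higher and 4 lower, 700 at an unadjusted p under 0.05). Only 2 passed by limma-voom or with the Control and PBM libraries alone, and of 16 settings Nfkbiz lost its call in 7, among them without Control replicate 2 or 4 and without PBM replicate 1 or 2, and Mt1, Fosb and Myl2 in 2.

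The mitochondrial lists did not move with PBM at 4 h by camera: cytochrome c oxidase, the enzyme often named as the target of PBM (adjusted p = 0.63), the other respiratory complexes (0.427), mitochondrially encoded genes (0.455) and mitochondrial biogenesis (0.844).

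At 24 h, immediate early genes were again below Control with PBM. Egr1, a zinc finger transcription factor (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984, plus strand), fell from 263 ± 28.5 to 68.4 ± 11.9 FPKM (log2 fold change -1.94 ± 0.16, limma adjusted p = 5.16e-06). Nr4a1 stood at 95.5 ± 12.9 FPKM in Control and was listed with PBM at 0 in 2 libraries and at up to 8.45 FPKM in the others (-5.07 ± 0.56, adjusted p = 9.04e-05). Fos fell from 341 ± 43.3 to 70.6 ± 28.4 FPKM (-2.35 ± 0.27, adjusted p = 0.000127), Junb from 148 ± 25.6 to 35.5 ± 7.98 (-2.04 ± 0.23) and Fosb from 124 ± 31.4 to 15.9 ± 6.41 (-2.94 ± 0.32). Socs3 fell from 25.5 ± 5.62 FPKM to 2.74, 0, 5.74 and 2.73 FPKM in the 4 PBM libraries (-3.06 ± 0.50, adjusted p = 0.0104). That call rests on few fragments, about 15 over the 4 Control libraries and about 2 over the 4 PBM libraries.

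Ptgs2, whose product makes prostaglandins, fell from 232 ± 11.9 to 115 ± 13.8 FPKM (-1.01 ± 0.11, adjusted p = 9.04e-05), and was the gene whose PBM effect differed between 24 h and 4 h (-1.05 ± 0.16, adjusted p = 0.00225). That difference did not pass by limma-voom or with only the Control and PBM libraries fitted. Of 100 drawn splits 24 gave as many calls, but those splits mix libraries of both times and also hold the differences between times. They therefore do not decide whether chance gave this call. Atf3 (-2.66 ± 0.46), Nfkbiz (-2.43 ± 0.37) and the clock regulator Bhlhe40 (-2.00 ± 0.36) fell as well, as did Ier3 (-1.67) and Klf6 (-1.27), named after their values were seen. Pex3 was listed at 0 with PBM and at 15.1 ± 11.3 FPKM in Control, and Avpi1 at 0 in Control and 17.0 ± 12.8 FPKM with PBM. 6430550D23Rik, named after its values were seen, was higher with PBM and listed at 0 in Control. Of the 17 immediate early genes, 8 fell (1 higher and 16 lower adjusted over the list alone, median -1.99, camera adjusted p = 0.000172 with an estimated correlation). Fosb, Nr4a1 and Nfkbiz were lower with PBM at both times (0.0041 genes expected from independent lists).

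The NF-kappaB list had 2 that fell, Ptgs2 and Nfkbiz (3 adjusted over the list alone, adjusted p = 0.365 with an estimated correlation). The interferon (median 0.33, adjusted p = 0.365 with an estimated correlation), A1 (0.32, adjusted p = 0.237 with an estimated correlation), antigen presentation (0.32, adjusted p = 0.211 with an estimated correlation), homeostatic (-0.52, adjusted p = 0.211 with an estimated correlation) and circadian lists (-0.39, adjusted p = 0.211 with an estimated correlation) also passed only with the preset correlation, with no member passing over the list alone but 2 circadian genes that were lower. Stat5a (-1.73 ± 0.76, adjusted p = 0.815) and Gfap (-0.90 ± 0.30, adjusted p = 0.597) did not pass over all genes, and Gfap passed over the 13 study genes alone (adjusted p = 0.0487). In all, 15 of 13278 genes passed by limma (2 higher and 13 lower, 790 at an unadjusted p under 0.05), 7 with the Control and PBM libraries alone and 9 without the last-listed libraries. Socs3 lost its call with a pseudocount of 0.1, with the 2 groups alone and without Control replicate 4, Bhlhe40 in 9 of 16 settings, Atf3 in 5, Pex3 and Avpi1 in 3 and Nfkbiz in 1, while Egr1, Fos, Fosb, Junb, Nr4a1 and Ptgs2 kept theirs under every setting tried.

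**Figure D3:**
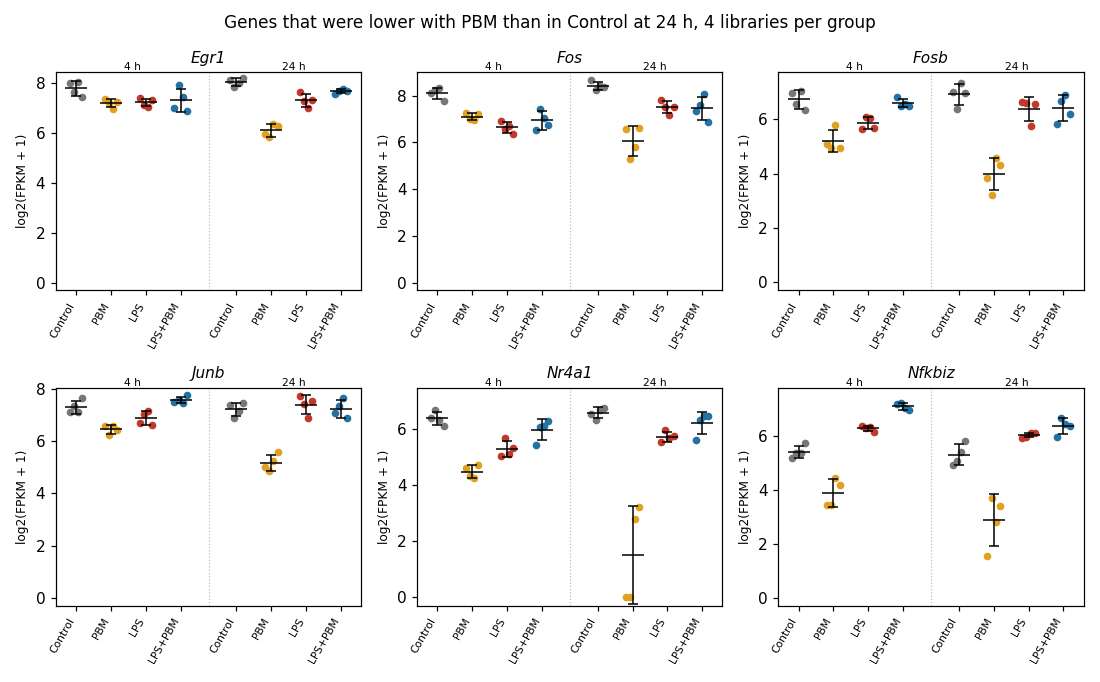
FPKM of Egr1, Fos, Fosb, Junb, Nr4a1 and Nfkbiz on the log2(FPKM + 1) scale (vertical axis) in the 8 groups (horizontal axis); points are the 4 libraries of a group, and the bar is their mean ± SD. All 6 genes are lowest with PBM alone at 24 h; Egr1 averages 68.4 FPKM there and 203 FPKM with LPS+PBM.

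Whether PBM acted differently with and without LPS was tested as an interaction. At 4 h, 4 genes passed, each with a PBM effect that was more positive with LPS: Nr4a1 (2.59 ± 0.36, limma adjusted p = 0.00967), Nfkbiz (2.35 ± 0.35), Fosb (2.27 ± 0.33) and Junb (1.53 ± 0.24). At 24 h, 7 passed (6 higher and 1 lower): Nr4a1 (5.56 ± 0.79), Fosb (2.95 ± 0.46), Fos (2.31 ± 0.38), Egr1 (2.31 ± 0.23), Junb (1.88 ± 0.32), Ptgs2 (1.17 ± 0.16) and, lower, Sprr2b. Socs3 had an interaction of 3.58 ± 0.93 at 4 h and 3.29 ± 0.71 at 24 h, which did not pass over all genes (adjusted p = 0.352 and 0.226) and passed over the 13 study genes alone (0.0154 and 0.00244). These Socs3 values rest in part on about 7 fragments over the PBM libraries at 4 h and about 2 at 24 h. As a list, immediate early genes had 3 of 17 that passed at 4 h (13 adjusted over the list alone, adjusted p = 0.00021 with an estimated correlation) and 5 at 24 h (16 higher and 1 lower adjusted over the list alone, adjusted p = 0.000843 with an estimated correlation).

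At 4 h the interferon list differed the other way (32 of 33 below 0, none passing and 4 lower adjusted over the list alone, median -0.77, adjusted p = 0.00621 with an estimated correlation). The homeostatic list was above 0 in all 20 members (none passing and 1 adjusted over the list alone, median 1.10, adjusted p = 0.0245 with an estimated correlation), the SOCS and STAT5 target list in 14 of 20 (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.0199 with an estimated correlation) and the circadian list in 13 of 15 (2 adjusted over the list alone, adjusted p = 0.0251 with an estimated correlation). Lists that passed only with the preset correlation were, at 4 h, A1 (adjusted p = 0.174 with an estimated correlation), antigen presentation (0.0815), hypoxia (0.0859), cholesterol synthesis (0.0535) and microglia markers (0.226), and at 24 h interferon (0.508), antigen presentation (0.346), growth factors (0.195) and circadian genes (0.195). Without the 6 last-listed libraries 1 gene passed at each time, and limma-voom called 7 and 9. At 24 h, 4 genes passed without PBM replicate 3, LPS replicate 2, LPS replicate 3 or LPS+PBM replicate 3, and of 24 settings Sprr2b lost its call in 19, Junb in 13 and Fos in 9, while at 4 h Junb lost it in 7.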

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

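Of the tests in this part, those on scaling, cell types and the other groups as causes of the immediate early pattern were chosen after seeing the result, while the regroupings of libraries were planned before it.

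A library was picked out where it lay far from the other 3 of its group. 12 of 144 sets of 4 held such a library, with 7.2 expected by chance for continuous values. A set with 3 libraries at 0 and 1 above 0 was always picked, and a set with all at 0 never. The 12 sets therefore do not measure an excess over chance. At 4 h with PBM these were Stat5a at 5.87 FPKM in replicate 2 (0 in the others), Cish at 32.96 in replicate 1 (2.71 to 7.61) and Tnf at 0 in replicate 1 (4.76 to 5.08). With LPS+PBM at 4 h, replicate 4 had a depth of 142470 fragments (134247 to 135280 in the others), and replicate 2 had Ccl2 at 2106.92 FPKM (1800.32 to 1823.31), Nos2 at 58.63 (38.8 to 41.85) and Lcn2 at 8.14 (23.01 to 24.42). At 24 h, Control replicate 1 had Stat5a at 1.95 (3.74 to 4.09) and Lcn2 at 8.29 (0 in the others), PBM replicate 1 had Stat5a at 1.94 (0 in the others), PBM replicate 2 had Il1b at 5.38 (0 in the others), and LPS replicate 2 had Socs3 at 14.14 (28.77 to 31.44). All were kept, and the cause was not tested.

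Effects that differed between groups or times were the interaction of LPS and PBM in 4 genes at 4 h and 7 genes at 24 h, the LPS effect in 86 genes between the times, and the PBM effect in 1 gene between the times. Among the study genes, the LPS effect was larger at 24 h for Il1b by 3.88 on the log2 scale, a value that depends on the pseudocount because Il1b was listed at 0 in all Control libraries at 24 h, and differed for Cxcl10 by -2.61.

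Each count was set against other splits of the same libraries, where the smallest possible result is 1 split, the real one. For LPS against Control, 1 of 35 splits called as many genes as the real 295 at 4 h (highest other 2) and the real 340 at 24 h (highest other 5). For lists it was 1 of 35 at 4 h (real 13, highest other 12) and 1 of 35 at 24 h (real 17, highest other 15). For LPS+PBM against LPS, 35 of 35 splits reached the real 0 at 4 h (highest other 2), as every split must, which says nothing on chance. For this comparison at 24 h, 17 of 35 reached the real 1 (highest other 3). For its lists, 2 of 35 reached the real 6 at 4 h (highest other 6) and 12 of 35 the real 1 at 24 h (highest other 5), so chance was not excluded for the lists at either time. For PBM against Control, 1 of 35 splits reached the real 6 genes at 4 h (highest other 3) and the real 15 at 24 h (highest other 5), and 1 of 35 reached the real 6 lists at 4 h (highest other 5) and the real 7 at 24 h (highest other 6).

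For the interaction, 1 of 100 drawn splits reached the real 4 genes at 4 h (highest other 2) and 3 of 100 the real 7 at 24 h (highest other 8). For lists it was 1 of 100 at 4 h (real 10, highest other 6) and 9 of 100 at 24 h (real 5, highest other 9), so chance was not excluded for the lists at 24 h. For differences between times, 1 of 100 reached the real 86 genes for LPS (highest other 49) and 24 of 100 the real 1 for PBM (highest other 85). For LPS+PBM against LPS, 100 of 100 reached the real 0 (highest other 301), as every split must. The splits for differences between times mix libraries of both times, so their counts also hold the differences between times.

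Immediate early genes were lower with PBM than in Control at 24 h. A scaling difference between libraries could do this, but after quantile normalization the list median was -2.06. Fewer cells of another type could do it, but the lowest median among the marker lists of other cell types was -0.09. The neuron, oligodendrocyte and endothelial lists had only 5, 6 and 9 tested members, and ependymal markers were not tested. For these cell types the medians do not decide the question. Control cultures that stand apart could do it. PBM was below LPS and LPS+PBM too, with list medians of -1.23 and -1.57 and 17 of 17 members below 0 in each. Both of those groups held LPS, which moved members either way at 24 h. Ier3 averaged 67.7 FPKM in Control and 206 FPKM with LPS, and Egr1 263 and 159 FPKM. The comparison therefore mixes LPS with PBM and does not exclude Control cultures that stand apart. These genes also answer within minutes to handling, medium and harvest, and nothing in the table separates that from the light, so this explanation may hold beside the medians of -2.06 and -1.23.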

How the results depend on the processing

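Of 182 named results that passed, 99 kept call and direction under every setting and 0 reversed; of 3088 settings tried on them, 407 lost the call. Counts that moved more than 1.5 times follow, and the cause was not tested. LPS+PBM against LPS at 4 h (0 genes) gave 1 with a pseudocount of 0.1, 16 by limma-voom, 1 without the last-listed 6 libraries, 1 without LPS replicate 2 and 2 without LPS+PBM replicate 2. PBM at 4 h (6) gave 2 by limma-voom and 2 with the 2 groups alone. The interaction at 4 h (4) gave 7 by limma-voom and 1 without the last-listed 6. LPS at 24 h (340) gave 159 without the last-listed 6. LPS+PBM against LPS at 24 h (1) gave 6 by limma-voom, 0 with the 2 groups alone, 0 without the last-listed 6, 2 without LPS replicate 4, 2 without LPS+PBM replicate 1 and 5 without LPS+PBM replicate 2. PBM at 24 h (15) gave 7 with the 2 groups alone and 9 without the last-listed 6. The interaction at 24 h (7) gave 4 with the replicate number as a block, 1 without the last-listed 6, and 4 without PBM replicate 3, LPS replicate 2, LPS replicate 3 or LPS+PBM replicate 3. The time difference of LPS (86) gave 52 with other samples in the fit and 42 without the last-listed 6. That of LPS+PBM against LPS (0) gave 3 by limma-voom, 5 without the last-listed 6, 1 without LPS 4 h replicate 1, LPS+PBM 4 h replicate 1 or 2, LPS 24 h replicate 2 or LPS+PBM 24 h replicate 1, and 2 without LPS+PBM 24 h replicate 2. That of PBM (1) gave 0 by limma-voom, 0 with other samples in the fit, 2 without Control 24 h replicate 2, PBM 24 h replicate 2 or PBM 24 h replicate 4, and 4 without PBM 24 h replicate 3. With an estimated correlation, lists that moved went from 6 to 1 for LPS+PBM against LPS at 4 h, 6 to 2 for PBM at 4 h, 10 to 5 for the interaction at 4 h, 1 to 0 for LPS+PBM against LPS at 24 h, 7 to 1 for PBM at 24 h and 5 to 1 for the interaction at 24 h. Lists for PBM at 4 h were 2 without PBM replicate 1 and 3 without PBM replicate 3; for PBM at 24 h 2 without Control replicate 2 and 4 without Control replicate 4; for the interaction at 24 h 1 without Control replicate 2; for LPS+PBM against LPS at 24 h 0 without LPS replicate 4, LPS+PBM replicate 2 or LPS+PBM replicate 3. The overlap at 24 h (1) was 2 without Control replicate 3, Control replicate 4, LPS replicate 4 or LPS+PBM replicate 1. The replicate block ended 13 and added 2 of 470 named results.

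Leaving out 1 library at a time, genes ranged, at 4 h, from 239 to 268 for LPS, 0 to 2 for LPS+PBM against LPS, 4 to 9 for PBM and 3 to 6 for the interaction; at 24 h from 242 to 280, 1 to 5, 10 to 18 and 4 to 8; and for the time differences from 61 to 88 for LPS, 0 to 2 for LPS+PBM against LPS and 1 to 4 for PBM. Lists ranged from 13 to 16, 5 to 7, 2 to 6 and 7 to 11 at 4 h and 16 to 18, 0 to 1, 2 to 6 and 1 to 6 at 24 h in the same order, and the overlap from 0 to 0 at 4 h and 1 to 2 at 24 h. The last-listed 6 libraries correlated in residuals at -0.024 to 0.010 with each other (14 pairs) and the other 26 at -0.047 to 0.043 (294 pairs). At 4 h the last-listed 6 held LPS replicate 1 and LPS+PBM replicate 2. At 24 h they held PBM replicate 2, LPS replicates 2 and 4 and LPS+PBM replicate 1. Leaving them out therefore also lowers the number of libraries in these groups.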

Other observations

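At 4 h with LPS, the metallothioneins Mt2 (log2 fold change 2.88 ± 0.30, limma adjusted p = 4.66e-06) and Mt1 (2.68 ± 0.29) rose, the 2 of 20 antioxidant and NRF2 targets that passed (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.159). Of 18 growth factors, Vegfa (1.36 ± 0.21), Tgfb2 (1.75 ± 0.41, a call lost in 7 of 16 settings) and Lif, also in the cytokine list, rose (3 higher and 2 lower adjusted over the list alone, adjusted p = 0.412), and Vegfa was the 1 hypoxia gene of 15 that rose (1 over the list alone, adjusted p = 0.119). Of 26 matrix genes, 5 rose and 1 fell (6 higher and 7 lower over the list alone, adjusted p = 0.711): the proteases Mmp13 (4.15 ± 0.37) and Mmp3 (4.67 ± 0.63) rose and Col1a1 (-0.58 ± 0.10) fell. Cell cycle (adjusted p = 0.325), cholesterol synthesis (0.197) and circadian lists (0.497) had no member that passed at 4 h.

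At 24 h, Tgfb1 rose (1.55 ± 0.33) beside Lif (2.70 ± 0.29) while Fgf1 fell (-2.90 ± 0.69, a call lost in 7 of 16 settings) (4 higher and 2 lower of 18 over the list alone, camera adjusted p = 0.759). The peroxidase Prdx1 rose (0.86 ± 0.13) and Gclc, which limits glutathione synthesis, fell (-1.03 ± 0.24, a call lost in 6 of 16 settings) (7 higher and 4 lower of 20 over the list alone, adjusted p = 0.088). The matrix proteoglycan Dcn rose by 1.54 on the log2 scale, from 145 ± 10.5 to 422 ± 18.5 FPKM, among fibroblast markers of which 1 rose and 2 fell (adjusted p = 0.41). Ccnd2 fell (-0.89 ± 0.14), the 1 of 20 SOCS and STAT5 targets that passed (1 higher and 2 lower over the list alone, adjusted p = 0.977), as did Bhlhe40 (-1.39 ± 0.36, a call lost in 8 of 16 settings) among circadian genes (2 lower over the list alone, adjusted p = 0.0756). Of 17 immediate early genes, Ier3 (1.63) and Fosl1 (3.57) rose and Egr1 (-0.73 ± 0.16, a call lost in 4 of 16 settings) fell (2 higher and 3 lower over the list alone, adjusted p = 0.0742). Cytochrome c oxidase (adjusted p = 0.821), the other respiratory complexes (0.835), mitochondrially encoded genes (0.168), mitochondrial biogenesis (0.816), glycolysis (0.977), heat shock (0.477), the unfolded protein response (0.477), cholesterol synthesis (0.206), ribosomal proteins (0.682), oligodendrocyte (0.477) and neuron markers (0.825) did not move.

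Of the tests below, those on microglia were chosen after seeing the result, and those on low p-values were written before it. LPS raised transcripts that microglia are known to make, such as Il1b. A larger share of microglial RNA could do this, but the median log2 fold change of microglia markers was -0.57 at 4 h and -0.58 at 24 h (mean -0.65 ± 0.21 and -0.50 ± 0.29, SE over members), although LPS may lower such markers by itself. Microglia present at a like share in all cultures could make part of the response: 17 of 20 markers were above 0 in Control at 4 h, with Ctss at 207 ± 15.1 FPKM and Csf1r at 67.8 ± 38.4 FPKM. The table cannot tell these apart from astrocytes as the source.

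LPS+PBM against LPS at 4 h had more genes at an unadjusted p under 0.05 than chance gives (997, or 7.53%), although none passed. Depth could do this, but after thinning to 1 depth the share was 7.13%. The thinning also rounded approximate fragments to whole numbers, which set the smallest values to 0. LPS replicate 3, already at the lowest depth, went from 10347 to 10021 genes above 0. The share therefore reflects the rounding as well as the depth. A single library could do it, but the lowest share with 1 library left out was 7.09%. Chance splits of the libraries reached it in 1 of 35 (real 997, highest other 823). A difference too small for this depth, from the light or from culture and processing, may be behind it, and the share of 7.13% does not tell which.

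The mean number of genes above 0 differed between LPS+PBM and LPS at 4 h by -149.75 (exact permutation p = 0.0286 over 70 assignments, the smallest possible, two-sided). After the same thinning and rounding it differed by -152.25 (exact permutation p = 0.0286). Group means at 4 h were 10609.5 for Control, 10630.5 for PBM, 10363 for LPS and 10213.25 for LPS+PBM, and at 24 h 10633.5, 10703.75, 10383.25 and 10334.75 in the same order. Only LPS+PBM against LPS at 4 h was tested. Rab4a, a regulator of endosome recycling chosen after its values were seen, was listed at 0 in all LPS libraries at both times and stood at 10.8 ± 7.08 FPKM with LPS+PBM at 4 h and 10.9 ± 5.38 FPKM at 24 h, which did not pass (limma adjusted p = 0.19 and 0.386).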
